A study of Mus musculus with 28 samples.

How the data were processed

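RNA was extracted from RAS and DNP53 transformed mouse embryonic fibroblasts the morning after overnight siRNA transfection with RNAiMAX, after leptomycin B at 20 ng/mL, or without treatment, per the labels' protocols. Libraries were made with a stranded poly(A) kit and sequenced as single reads of 100 bp. Per the submitters' processing notes, the tools were CASAVA 1.8.2, FastQC, TopHat2 2.0.13, Bowtie2 2.2.3 and HTSeq 0.6.1p1 with genome build mm10. The strand setting and the gene annotation are not given in the sources used here, so overlapping and antisense genes, and near-identical family members, may share reads. The authors deposited raw counts per gene in 1 table, 24079 rows by 28 libraries. Every column was used, and columns were matched to samples by the sample number in the labels. The 22 rows without a gene ID (at most 0.0137% of a library) were kept and passed through the same filter as the others, and 17 symbols occurred more than once. Gene IDs were matched to the GRCm38.p6 annotation, the assembly of mm10, for 23977 rows, which gave the coordinates. The titles carry an n of 3 or 4 whose meaning, such as pooling before sequencing, is not given in the sources used here. Each library was treated as 1 sample. No pair of the 378 pairs of libraries was within sampling noise (lowest chi-square per degree of freedom 14.6).

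Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM size factors, and a robust quasi-likelihood fit of all 28 libraries in 15 groups, with 17 coefficients and 11 residual degrees of freedom, since most groups hold 2 libraries and share the estimate of spread. The clone, or the matched pair for the mCherry lines, was a block because both arms of each comparison hold the same clones. As a check, libraries of the same clone deviated together in all 56 tagged pairs (lowest correlation 0.834) and 6 untagged pairs (0.862), and in the 3 mCherry pairs (0.251). Tests used the contrasts named in the results with Benjamini-Hochberg adjusted p under 0.05; pooled contrasts average the siRNAs of a kind. Standard errors are the log2 fold change divided by the square root of the F statistic. The comparison of tagged with untagged clones used the 4 SCR libraries alone, with 13233 genes and no block. The biological coefficient of variation was 14.6%. CPM values were computed from the deposited counts with TMM size factors; log2 CPM used a prior count of 2. Counts near 0 carry the largest errors.

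The contrasts, 22 gene lists and the alternatives were fixed before the data were examined. Of the lists, 20 were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 160 tests of list and comparison. Myogenic markers had under 3 tested members, and 0 genes of the mitochondrial transcript list were in the table, so neither was tested. Camera called 27 of the 160, and 0 with an estimated correlation. In the same tests fry called 22 by direction, 14 of them camera calls, and 62 for change in either direction, 18 of them camera calls. A count adjusted over the list alone uses the same edgeR p-values adjusted over the members. Named genes were Ccnd1 (and Xpo1 for leptomycin B), the 8 largest and 8 smallest log2 fold changes among called genes with a mean of at least 1 CPM and the same sign in every block, and up to 4 members with the smallest p from each list discussed. A few genes that the rule selects are not reported here. Ccnd2, and genes named as called with all 5 siRNAs, were chosen after their values were seen. A list member whose name differs in the table is written as in the table.

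Alternatives were relative log expression size factors, non-robust dispersion, no filter and a stricter filter, no replicate block, only the libraries of a comparison, DESeq2 1.42.0, and leaving out each library in turn. Added after seeing the data were fits without the 4 libraries with over 2% Rn45s, without the Rn45s row, with untreated cells as control, with genes of at least 1 CPM, with Ccnd1 taken out of the gene lists, and, for genes called with all 5 siRNAs, without SCR clone 12. The edgeR fit of all libraries and its pooled contrasts were tested on simulated data with 100 genes changed per size. The gene list tests, DESeq2, the single siRNAs and the comparison of tagged with untagged clones were not. At log2 changes of 1 and 2, edgeR recovered 61 and 70 of 100 genes for tag siRNA in tagged clones, 64 and 79 for cyclin D1 siRNA, 75 and 81 for their difference, 69 and 78 in untagged clones, 40 and 72 for the tagged minus untagged response. It recovered 70 and 90 for the mCherry constructs, 58 and 84 for leptomycin B and 57 and 85 for SCR against untreated. There were 1 to 12 false calls among 113 to 168 calls per comparison, with 14847 to 14876 genes tested. The most were 12 of 154 calls, for SCR against untreated.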

Results

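Transcripts were counted in 28 RNA-seq libraries of mouse embryonic fibroblasts transformed with RAS and DNP53. Cyclin D1 carried a tag in clones 12 and 14 and was untagged in clones 18 and 25. Each tagged clone gave 1 library for each of 8 treatments. These were no treatment, leptomycin B (an inhibitor of the nuclear exporter XPO1), the control siRNA labelled SCR, siRNAs against the FLAG and HA epitope tags, and 3 siRNAs against cyclin D1 itself that the labels call Qiagen, Nature and Life. Each untagged clone gave 1 library with SCR, FLAG and HA siRNA. Clone 18 carrying mCherry, or mCherry flanked by FLAG and HA, gave 3 further libraries for each construct, 2 with HA siRNA and 1 with FLAG siRNA. Total counts ran from 26558256 to 81512769 per library, and 15099 genes were tested. Most groups held 2 libraries, 1 per clone. As the level of each clone was fitted as a block, the p-values measure the spread of these libraries around the clone and treatment levels, not the spread between clones, except where tagged and untagged clones were compared. The clones differed strongly. The leading 3 principal components held 57.2%, 28% and 10.9% of the variance of 1000 genes and separated the clones. The SCR library of clone 12 had the highest total and the fewest genes with counts, 14132. There, 307 genes were at 0 for which its clone's other libraries predicted at least 10 counts, against at most 16 genes in any of the other 21 clone libraries. The ribosomal RNA precursor Rn45s took over 2% of the counts in 4 libraries: Life clone 14 (3.48%), mCherry HA 2 (2.75%), Nature clone 14 (2.42%) and HA clone 12 (2.22%).

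Ccnd1, the gene of cyclin D1 (gene 12443, chromosome 7, 144929931 to 144939831, mm10), fell with each of the 5 targeting siRNAs in tagged clones. Its mean was 1210 ± 112 CPM (SD, n = 2) with SCR siRNA, 156 ± 35.2 with FLAG, 221 ± 2.15 with HA, 326 ± 4.23 with Qiagen, 56.9 ± 9.64 with Nature and 63.1 ± 15 with Life. Pooled, the tag siRNAs lowered it 6.5-fold (log2 fold change -2.70, SE 0.19, edgeR adjusted p = 3.45e-07; -2.92 and -2.49 in the 2 clones). The cyclin D1 siRNAs lowered it 11.4-fold (-3.51, SE 0.17, adjusted p = 1.12e-09; -3.76 and -3.29). In untagged clones the mean was 1320 ± 11.7 CPM with SCR, 1120 ± 150 with FLAG and 1270 ± 25.9 with HA siRNA. A difference was not detectable (log2 fold change -0.15, SE 0.20, adjusted p = 0.873). The response of tagged clones exceeded that of untagged clones (difference -2.55, SE 0.28, adjusted p = 0.000804). The call ended without the SCR library of untagged clone 25 (-2.49, adjusted p = 0.0664). Ccnd1 stood at 1240 ± 330 CPM in untreated cells and 1020 ± 372 with leptomycin B, and between 1080 and 1340 in the group means of the mCherry lines.

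**Figure D1:**
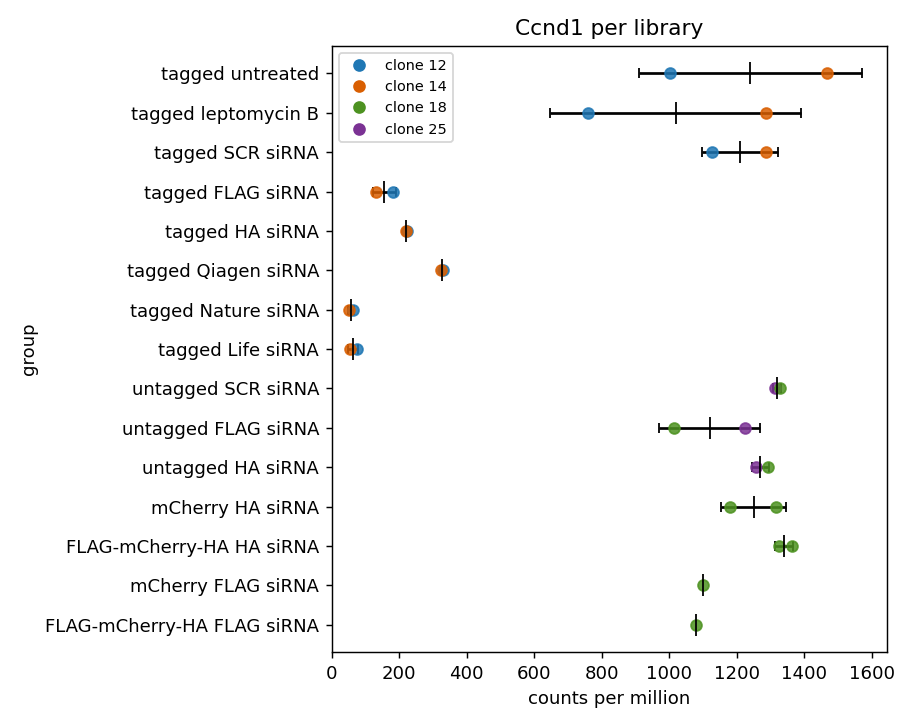
Read counts as CPM of Ccnd1 in each library, by group, with points coloured by clone and bars giving the mean with its SD where a group has 2 libraries. Ccnd1 lies between 56.9 and 326 CPM on average in the 5 siRNA groups of the tagged clones that target it or its tag, and at 1020 or more in the other group means.

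Each siRNA was set against SCR to ask which ones drive the pooled comparisons. The remaining Ccnd1 was 13% with FLAG, 18.3% with HA, 27% with Qiagen, 4.73% with Nature and 5.24% with Life siRNA, against 84.6% and 96.5% with FLAG and HA siRNA in untagged clones. The related D-type cyclins moved with single siRNAs. Ccnd2 fell with Nature siRNA (log2 fold change -2.21, SE 0.28, adjusted p = 5.14e-05), from 233.7 and 611.2 CPM to 45.75 and 145. Nature differed from the mean of the other 4 targeting siRNAs (-2.24, SE 0.25, adjusted p = 9.34e-06). Ccnd3 fell with Life siRNA (-1.90, SE 0.22, adjusted p = 2.86e-05), from 86.02 and 127 CPM to 24.3 and 32.68. Life differed from the other 4 (-1.85, SE 0.19, adjusted p = 6.26e-06). Ccnd3 was -0.72 with Qiagen siRNA (adjusted p = 0.0562). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, fell with all 5: -1.30 with FLAG (adjusted p = 0.000106), -1.76 with HA (6.22e-06), -1.09 with Qiagen (0.000181), -0.65 with Nature (0.00958) and -0.84 with Life (0.00158). It also fell with FLAG and HA siRNA in untagged clones (-1.22, adjusted p = 0.000191, and -1.86, adjusted p = 4.28e-06). edgeR called 328 genes with FLAG, 620 with HA, 805 with Qiagen, 1293 with Nature and 1251 with Life siRNA in tagged clones. In untagged clones it called 305 with FLAG and 326 with HA. Without the clone as a block these counts were 13, 31, 76, 116, 116, 14 and 26.

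**Figure D2:**
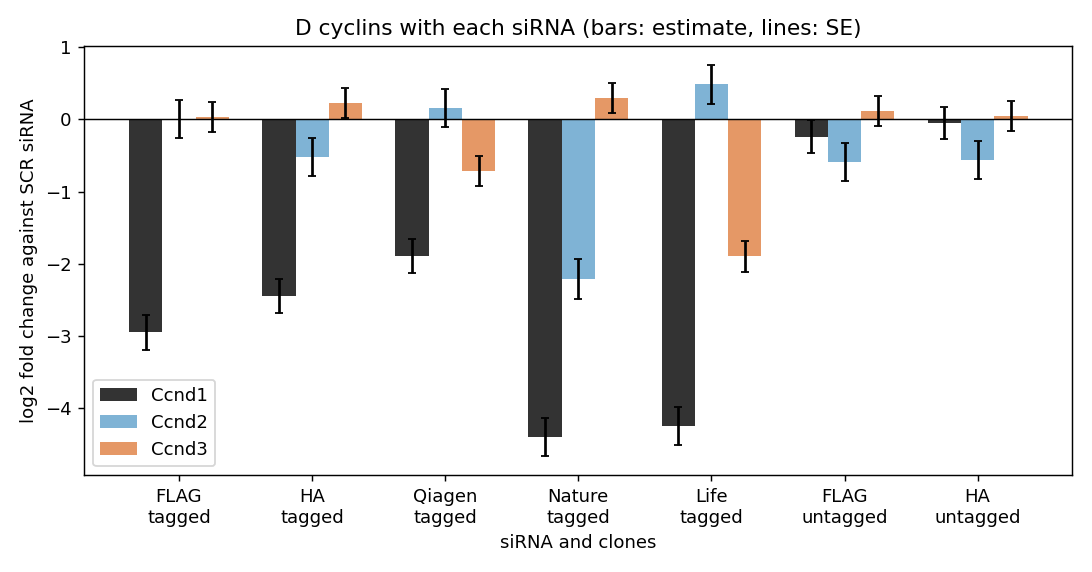
Log2 fold change against SCR siRNA of Ccnd1, Ccnd2 and Ccnd3 for each siRNA in tagged and untagged clones, as bars with the standard error of the edgeR fit. Ccnd2 reaches -2.21 with Nature siRNA and Ccnd3 reaches -1.90 with Life siRNA.

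FLAG and HA siRNA in tagged clones were compared with SCR siRNA to ask what follows removal of cyclin D1 through its tag. Besides Ccnd1, Cdkn1a fell (log2 fold change -1.53, SE 0.12, adjusted p = 2e-06; -0.51, adjusted p = 0.00671 against untreated cells). So did Slc37a4, the glucose-6-phosphate transporter of the endoplasmic reticulum (-1.54, SE 0.18, adjusted p = 7.45e-05), Scrn1 (-1.87, SE 0.25, adjusted p = 0.000218) and Flt1, a receptor for vascular endothelial growth factor (-1.42, SE 0.22, adjusted p = 0.000728). Taldo1, the transaldolase of the pentose phosphate pathway, rose (1.66, SE 0.14, adjusted p = 4.11e-06), with Pex6, a peroxisome assembly factor (1.90, SE 0.20, adjusted p = 2.75e-05), and Top1mt, the mitochondrial topoisomerase (1.73, SE 0.19, adjusted p = 3.92e-05). Higher too were Oscp1 (2.07, adjusted p = 7.45e-05), Ctxn1 (2.06, adjusted p = 8.11e-05) and Cnnm2 (1.71, adjusted p = 8.28e-05). Many of these genes were also called in the same direction in untagged clones, where Ccnd1 was not called. There Cdkn1a was at -1.54, Slc37a4 at -1.43, Scrn1 at -1.9, Taldo1 at 1.36, Pex6 at 1.52 and Top1mt at 1.64. Oscp1 was at 1.5, Ctxn1 at 1.72 and Cnnm2 at 1.28. Only Ccnd1 was called in the test of the difference between tagged and untagged clones, which recovered 40 of 100 genes at a log2 difference of 1 in simulation. Slc25a30 (-1.84, adjusted p = 0.000907), Pla2g4c (-1.52, adjusted p = 0.00437), Nrg2 (-1.53, adjusted p = 0.0416) and Oasl1 (1.98, adjusted p = 0.00934) lost their calls without the SCR library of clone 12 (adjusted p = 0.0787, 0.408, 0.547 and 0.871). Pitx1 (1.73, adjusted p = 0.00366) lost its call without the FLAG, HA or SCR library of clone 14 (adjusted p = 0.435, 0.922 and 0.351). Oasl1 lost it also without FLAG clone 12 (0.941), and Nrg2 without FLAG clone 12, FLAG clone 14 or HA clone 14 (0.0928, 0.147 and 0.314). In all, edgeR called 583 genes, 307 higher and 276 lower. Of these, 580 had the same sign in both clones and 81 and 47 changed at least 2-fold. At an unadjusted level, 3071 genes had an unadjusted p under 0.05. Of the 583, 26 were at 0 in the SCR clone 12 library, and 619 were called when testing was restricted to the 11772 genes with a mean of at least 1 CPM. More genes than in the main fit were called without SCR clone 14, where SCR clone 12 stood alone as control. The count was 113 without SCR clone 12, 306 without FLAG clone 14, 309 without FLAG clone 12, 328 without HA clone 14, 353 without HA clone 12 and 377 without the libraries with over 2% Rn45s. It was 32 without the clone block, 1024 with DESeq2, 3283 when only the libraries compared were fitted and 4921 against untreated cells in place of SCR, a control chosen after seeing the data.

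Among the gene lists fixed before the data were examined, DNA replication and E2F target genes mostly had lower estimates with tag siRNA, and few were called. Of them, 29 of 30 had a negative log2 fold change and 3 fell past the test, or 11 when adjusted over the list alone (camera adjusted p = 1.02e-07; adjusted p = 0.596 with an estimated correlation). They included Uhrf1, which maintains DNA methylation at replication (-0.64, edgeR adjusted p = 0.00466), and Cdc6, a replication licensing factor (-0.67, adjusted p = 0.00485). Both calls ended without SCR clone 12 (adjusted p = 0.274 and 0.378). Of 15 D cyclins and G1 regulators, 4 fell, and 4 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00337; adjusted p = 0.14 with an estimated correlation). The list holds Ccnd1 itself, and without it the list was not called (camera adjusted p = 0.0604, chosen after seeing the data). Beside Ccnd1 and Cdkn1a they held Rb1, the retinoblastoma protein that cyclin D1 and its kinases inactivate (-0.74, SE 0.13, edgeR adjusted p = 0.0022). Rb1 was also called lower in untagged clones (-0.60, adjusted p = 0.0151), where Ccnd1 was not called. Mitosis genes were negative for 19 of 25 members, and 1 fell, or 1 when adjusted over the list alone (camera adjusted p = 0.00153; adjusted p = 0.806 with an estimated correlation). Cholesterol biosynthesis genes were positive for 20 of 21 members. Fdps, farnesyl diphosphate synthase, rose (0.91, SE 0.13, edgeR adjusted p = 0.000554), and 12 members rose when adjusted over the list alone (camera adjusted p = 1.15e-05; adjusted p = 0.589 with an estimated correlation). Of 5 epithelial markers 1 rose, and 2 when adjusted over the list alone (camera adjusted p = 0.00977; adjusted p = 0.596 with an estimated correlation). The apoptosis lists were not called. Of 25 caspases and pro-apoptotic genes, 1 rose and 1 fell, or 2 and 3 when adjusted over the list alone (camera adjusted p = 0.968). Among them Bcl2l11, which encodes the death activator BIM, fell (-0.61, SE 0.12, edgeR adjusted p = 0.00602). So did Bcl2, its anti-apoptotic partner in a list of 11 (-0.74, SE 0.15, adjusted p = 0.00827; camera adjusted p = 0.593 for the list). Both calls were lost without SCR clone 12 (adjusted p = 0.148 and 0.109). Lists without a camera call were p53 targets (adjusted p = 0.546), interferon response (0.584), integrated stress and unfolded protein response (0.0984) and RAS-MAPK output (0.968). Also uncalled were NF-kB targets (0.908; median log2 fold change 0.09 against a lower direction in camera), extracellular matrix and contractile genes (0.975), glycolysis and hypoxia (0.626), and nuclear export and import (0.165). The same held for heat shock proteins (0.163), RNA interference machinery (0.111), and macrophage (0.485), endothelial (0.983) and neural markers (0.629).

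The 3 siRNAs against cyclin D1 itself addressed the same question through another sequence. Nature siRNA also lowered Ccnd2 (log2 fold change -2.21) and Life siRNA also lowered Ccnd3 (-1.90). The pooled changes therefore cannot be assigned to loss of cyclin D1 alone. DNA replication genes had lower estimates across the list, and a part of them was called. All 30 E2F targets had negative log2 fold changes and 10 fell past the test, or 20 when adjusted over the list alone (camera adjusted p = 1.56e-15; adjusted p = 0.343 with an estimated correlation). Ccne1, the gene of cyclin E1 (log2 fold change -1.004, SE 0.11, edgeR adjusted p = 4.11e-05), and Mcm5, a subunit of the replicative helicase (-0.88, SE 0.10, adjusted p = 4.24e-05), kept their calls whichever library was left out. Cdc6 (-0.77, adjusted p = 0.000873) and Uhrf1 (-0.68, adjusted p = 0.00152) lost theirs without SCR clone 12 (adjusted p = 0.148 and 0.156). Against untreated cells in place of SCR, a control chosen after seeing the data, Ccne1, Mcm5, Cdc6 and Uhrf1 stayed lower (-0.38, -0.63, -0.69 and -0.75). That contrast also holds transfection and possibly another day. Of its 3584 called genes 2138 were lower, so it does not isolate the loss of cyclin D1. All 25 mitosis genes were negative and 10 fell, or 15 when adjusted over the list alone (camera adjusted p = 1.46e-11; adjusted p = 0.596 with an estimated correlation). Among them were Kif20a, a kinesin of cytokinesis (-0.60, edgeR adjusted p = 0.00591), Prc1, which bundles spindle midzone microtubules (-0.59, adjusted p = 0.0145), and Foxm1, a transcription factor of mitotic genes (-0.45, adjusted p = 0.0159), whose calls ended without SCR clone 12 (adjusted p = 0.21, 0.319 and 0.4). Of 15 D cyclins and G1 regulators 5 fell, and 5 when adjusted over the list alone (camera adjusted p = 0.000399; adjusted p = 0.132 with an estimated correlation), and without Ccnd1 in the list camera gave an adjusted p = 0.0179 (adjusted p = 0.514 with an estimated correlation). Cdkn1a was among them (-0.86, SE 0.12, edgeR adjusted p = 0.000218; 0.16 and adjusted p = 0.362 against untreated cells). Epithelial markers were positive for all 5 members, of which 1 rose when adjusted over the list alone (camera adjusted p = 0.0251; adjusted p = 0.623 with an estimated correlation). Cholesterol biosynthesis genes, mostly positive with tag siRNA, were negative here for 13 of 21 members (camera adjusted p = 0.269). Of them 1 was called higher and 2 lower, or 2 and 2 when adjusted over the list alone. The caspase and pro-apoptotic list had a camera adjusted p of 0.968 and the anti-apoptotic list 0.968.

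Outside the lists, genes higher with the cyclin D1 siRNAs than with SCR were Taldo1 (log2 fold change 1.74, SE 0.14, adjusted p = 1.01e-06), F2r, a thrombin receptor (1.72, SE 0.11, adjusted p = 7.24e-08), Top1mt (1.79, SE 0.18, adjusted p = 1.33e-05), Pex6 (1.797, SE 0.19, adjusted p = 1.73e-05) and Ctxn1 (2.07, SE 0.24, adjusted p = 4.24e-05). All of them were also called higher with tag siRNA in untagged clones (1.36, 1.73, 1.64, 1.52 and 1.72), where Ccnd1 was not called. F2r and Top1mt were also lower with SCR siRNA than without treatment. Lower with the cyclin D1 siRNAs were Asf1b, a histone chaperone of replicating chromatin (-1.54, SE 0.12, adjusted p = 6.81e-07), and Fam114a2 (-1.31, SE 0.11, adjusted p = 2.34e-06). F2r turned to -0.39 (adjusted p = 0.00901) against untreated cells. Without SCR clone 12 the calls ended for Hlf (1.94; adjusted p = 0.0859), Arrdc4 (1.73; 0.197), Adamts12 (2.32; 0.944), Mreg (-1.40; 0.205), Eif4ebp2 (-1.29; 0.0821), Sprr1a (-1.21; 0.123), Lrrc10b (-1.21; 1) and Eif5a2 (-1.21; 0.39). Several of these also lost their calls without other libraries. These were Adamts12 without each clone 12 siRNA library (adjusted p = 0.198 without Life, 1 without Nature and 1 without Qiagen), and Sprr1a without SCR clone 14 (0.136) or Qiagen clone 14 (0.0823). They were also Lrrc10b without any library but SCR clone 14 (0.0509 to 1) and Eif5a2 without SCR clone 14, Life clone 14, Nature clone 12 or Qiagen clone 14 (0.0539 to 0.0647). edgeR called 815 genes, 405 higher and 410 lower, with 112 and 63 at least 2-fold. Of these, 802 had the same sign in both clones, and 3014 genes had an unadjusted p under 0.05. Of the 815, 37 were at 0 in the SCR clone 12 library, and 804 were called among genes of at least 1 CPM. More genes than in the main fit were called without SCR clone 14, where SCR clone 12 stood alone as control. The count was 97 without SCR clone 12, 40 without the clone block, 65 when only the libraries compared were fitted, 1280 with DESeq2 and 3584 against untreated cells.

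Tag and cyclin D1 siRNAs were also compared directly within the tagged clones, a contrast that uses no SCR library. Ccnd1 was higher with tag siRNA (log2 difference 0.82, SE 0.15, adjusted p = 0.00171). The fall was deeper than with FLAG (-2.95) or HA (-2.45) for Nature (-4.40) and Life (-4.25) but shallower for Qiagen (-1.89). Without the libraries with over 2% Rn45s it was 0.58 (adjusted p = 0.136). Of the cholesterol biosynthesis genes, 13 of 21 were higher with tag siRNA, or 17 when adjusted over the list alone (camera adjusted p = 2.98e-13; adjusted p = 0.14 with an estimated correlation). They included Idi1, isopentenyl diphosphate isomerase (0.86, SE 0.09, edgeR adjusted p = 7.93e-06), Sqle, squalene epoxidase (0.57, SE 0.09, adjusted p = 0.000396), and Cyp51, lanosterol demethylase (0.61, SE 0.10, adjusted p = 0.000789). Ccne1 (0.88, SE 0.09, adjusted p = 1.26e-05) and Mcm5 (0.54, SE 0.08, adjusted p = 0.000427) were higher with tag siRNA among 4 of 30 E2F targets, and 4 when adjusted over the list alone (camera adjusted p = 0.0207; adjusted p = 0.81 with an estimated correlation). So were 2 of 25 mitosis genes, or 8 when adjusted over the list alone (camera adjusted p = 0.000846; adjusted p = 0.806 with an estimated correlation). Of the D cyclins and G1 regulators 3 were higher and 3 lower, or 5 and 3 when adjusted over the list alone (camera adjusted p = 0.629). Among these were Ccnd3 at 0.90 (edgeR adjusted p = 0.000327) and Rb1 at -0.88 (adjusted p = 2.06e-05). The most changed genes higher with tag siRNA included Fam114a2 (1.46, SE 0.10, adjusted p = 8.17e-08), Asf1b (1.31, adjusted p = 3.57e-07), Cops8 of the COP9 signalosome (1.21, adjusted p = 7.49e-08) and Them6 (1.19, adjusted p = 0.000261). Lower were Scrn1 (-1.88, adjusted p = 1.65e-05), Lin28b, an inhibitor of let-7 maturation (-1.64, adjusted p = 8.14e-05), Manba, the lysosomal beta-mannosidase (-1.58, adjusted p = 3.14e-06), Polr3g of RNA polymerase III (-1.48, adjusted p = 1.16e-06), Prr13 (-1.46, adjusted p = 2.65e-06) and Fkbp1a (-1.34, adjusted p = 2.98e-06). Sprr1a (1.27) and Cdkn2d (1.10) lost their calls without HA clone 14 (adjusted p = 0.101 and 0.0654), Rfx2 (1.20) without FLAG clone 14 or HA clone 14 (0.102 and 0.106). Hmga1 (1.25) lost its call without any one of the 5 clone 12 siRNA libraries (adjusted p = 0.0586 to 0.174) and Peg3 (-1.45) without any one of the 5 from clone 14 (0.0739 to 1). Map3k13 (-1.43) lost it without FLAG, Life or Qiagen of clone 12 or FLAG, HA or Nature of clone 14 (0.0734 to 0.217).

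This direct comparison gave 1056 genes, 589 higher and 467 lower with tag siRNA. Of these, 16 and 39 differed at least 2-fold, 1052 had the same sign in both clones, and 3149 genes had an unadjusted p under 0.05. Regrouping the 5 siRNAs into sets of 2 and 3 gave as many genes or more in 5 of 10 groupings, the real one included, with 3733 for Qiagen and Life together and 3580 for HA and Nature. With the clone as block and the siRNAs of a kind as replicates, 9 genes were called. Against the mean of the other 4, Life siRNA differed at 2145 genes, Qiagen at 2071, Nature at 1500, HA at 734 and FLAG at 200. The 1056 became 451 without FLAG clone 14, 476 without HA clone 14, 617 without FLAG clone 12 and 312 without the libraries with over 2% Rn45s, which include HA clone 12, Nature clone 14 and Life clone 14. The count was 88 without the clone block and 1676 with DESeq2.

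The same FLAG and HA siRNAs were compared with SCR siRNA in untagged clones, where cyclin D1 has no tag to target. There is no untreated library of these clones, so the contrast alone does not tell an effect of these siRNAs from one of SCR. In tagged clones SCR itself differed from no treatment at F2r (-2.11), Top1mt (-1.45) and Cdkn1a (1.02). Polr3g, Prr13 and Scrn1 were lower with tag than with cyclin D1 siRNA in tagged clones (-1.48, -1.46 and -1.88), a comparison without SCR, and were not called between SCR and no treatment (adjusted p = 0.307, 0.24 and 0.728). Cdkn1a was lower with tag siRNA here as well (log2 fold change -1.54, SE 0.12, adjusted p = 2.91e-06), with Polr3g (-1.49, SE 0.15, adjusted p = 1.77e-05), Rpp25l, a relative of an RNase P subunit (-1.41, SE 0.16, adjusted p = 4.46e-05), and Prr13 (-1.46, SE 0.16, adjusted p = 4.46e-05). F2r (1.73, SE 0.11, adjusted p = 2.27e-07) and Top1mt (1.64, SE 0.19, adjusted p = 7.7e-05) were higher. These 6 genes were called whichever library was left out. Without the SCR library of clone 18 the calls ended for Dnajc30 (1.77; adjusted p = 0.0535), Ctxn1 (1.72; 0.0567), Hic1, a transcriptional repressor (1.60; 0.274), Pitx1 (2.17; 1), Ccdc88b (2.27; 1), Ier5l (1.64; 0.167), Scrn1 (-1.90; 0.0567), Slc37a4 (-1.43; 0.0777) and Slc25a30 (-1.43; 0.611). Without the SCR library of clone 25 they ended for C1qtnf6 (-1.77; 0.0511), Ctxn1 (0.0604), Hic1 (0.117), Ier5l (0.69) and Slc25a30 (0.0749). Leaving out FLAG clone 18 ended those of Ccdc88b (0.193), Pitx1 (0.909), Ier5l (0.282) and Slc25a30 (0.0742). Leaving out HA clone 18 ended that of Ccdc88b (0.145) and HA clone 25 that of Ier5l (0.11). Of 15 D cyclins and G1 regulators 2 were lower, Cdkn1a and Rb1, and 2 when adjusted over the list alone (camera adjusted p = 0.249). Rb1 lost its call without SCR clone 18 (0.531), SCR clone 25 (0.197), FLAG clone 18 (0.0692), FLAG clone 25 (0.0555) or HA clone 18 (0.052). Cholesterol biosynthesis genes were positive for 18 of 21 members, with Fdps called (0.73, adjusted p = 0.00319; 0.429 without SCR clone 18) or 2 when adjusted over the list alone (camera adjusted p = 0.000259; adjusted p = 0.596 with an estimated correlation). E2F targets were negative for 26 of 30 members, 3 of them called when adjusted over the list alone (camera adjusted p = 0.0016; adjusted p = 0.806 with an estimated correlation). edgeR called 404 genes, 182 higher and 222 lower, with 32 and 34 at least 2-fold. All 404 had the same sign in both clones, and 1817 genes had an unadjusted p under 0.05. The count was 27 without SCR clone 18, 165 without SCR clone 25, 188 without FLAG clone 18, 21 without the clone block, 80 when only the libraries compared were fitted and 691 with DESeq2.

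Most genes called with tag siRNA in untagged clones were also called in tagged clones. Of the 404 genes called in untagged clones, 301 were also called with the same sign in tagged clones, 144 higher and 157 lower, against 7.76 for independent lists of these sizes. No gene was called in opposite directions, and the comparisons share no library. Over those 404 genes, 99% had the same sign in tagged clones and the correlation of log2 fold changes was 0.955, across genes, which are not independent replicates. These genes were chosen by their calls in untagged clones. Over the 583 genes called in tagged clones, 95.9% had the same sign and the correlation was 0.509. Over all 15099 genes tested it was 0.172 (Spearman 0.454). All 301 shared genes had a mean of at least 1 CPM. Cdkn1a, Scrn1, Slc37a4, Ctxn1 and Top1mt were among the most changed in both. The test of the difference itself called 1 gene, Ccnd1 (log2 difference -2.55, SE 0.28, edgeR adjusted p = 0.000804), and DESeq2 called 1. An unadjusted p under 0.05 was seen for 403 genes, less than a 0.05 share of the 15099 tested. In simulation this test recovered 40 of 100 genes at a log2 difference of 1, the lowest of the comparisons. The lack of other calls therefore does not show that the responses were equal. Relative to other genes, E2F targets were more negative in tagged clones, 27 of 30 members (camera adjusted p = 0.0015; adjusted p = 0.806 with an estimated correlation). So were 24 of 25 mitosis genes (camera adjusted p = 0.00642; adjusted p = 0.807 with an estimated correlation). In the D cyclins and G1 regulators 1 member, Ccnd1, was called, or 1 when adjusted over the list alone (camera adjusted p = 0.017; adjusted p = 0.293 with an estimated correlation). Without Ccnd1 that list had a camera adjusted p of 0.299. All 5 epithelial markers were more positive (camera adjusted p = 0.0361; adjusted p = 0.671 with an estimated correlation). The count was 0 without the SCR library of untagged clone 25, and 28 without the SCR library of tagged clone 14, of which 17 were at 0 in the SCR clone 12 library that remained.

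**Figure D3:**
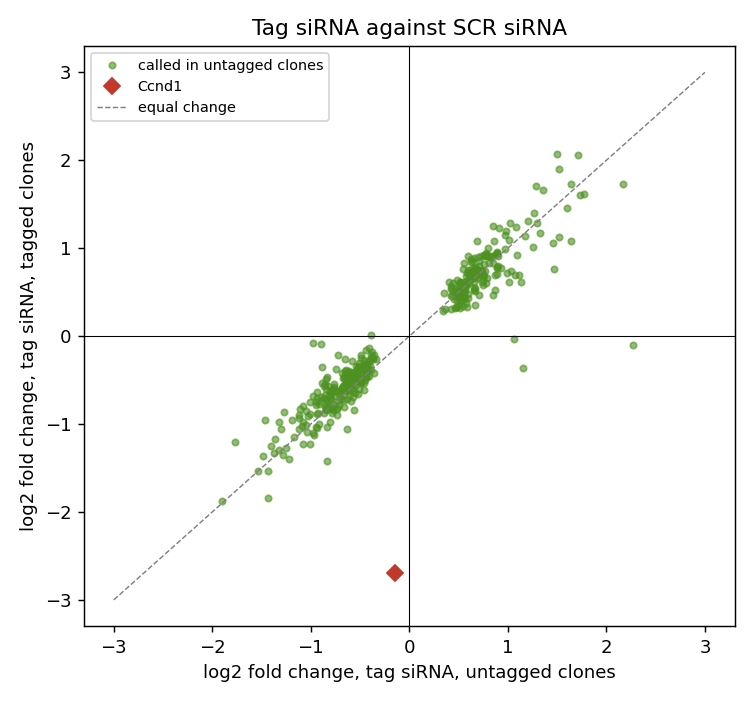
Log2 fold change with tag siRNA against SCR in untagged clones (horizontal axis) and in tagged clones (vertical axis) for the 404 genes called in untagged clones, as points, with Ccnd1 added as a diamond and a dashed line of equal change. The points follow the line, with a correlation of 0.955 across these selected genes, and Ccnd1 lies at -0.15 and -2.70. The correlation was 0.509 over the genes called in tagged clones and 0.172 over all 15099 genes tested, which are not drawn.

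Clone 18 with FLAG-mCherry-HA was compared with clone 18 with mCherry, both under HA or FLAG siRNA, to ask what targeting a tagged transcript other than cyclin D1 does. These lines have no SCR library, so targeting the tagged transcript and carrying another construct cannot be told apart. No member of the interferon response list was called, and 25 of 30 were negative, with a median log2 fold change of -0.35 and 1 lower when adjusted over the list alone (camera adjusted p = 0.000762; adjusted p = 0.596 with an estimated correlation). Cholesterol biosynthesis genes were positive for 16 of 21 members (camera adjusted p = 0.00848; adjusted p = 0.671 with an estimated correlation), and nuclear export and import genes for 14 of 18 (0.03; adjusted p = 0.623 with an estimated correlation). Ccnd1 had a log2 fold change of 0.06 (SE 0.19, edgeR adjusted p = 0.918). No single gene was called by edgeR over the 3 pairs (0 genes; 1390 at an unadjusted p under 0.05), while DESeq2 called 15 and edgeR without a filter on low counts 2.

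Leptomycin B blocks the exporter XPO1 and so keeps many proteins in the nucleus. It was compared with no treatment in the tagged clones. Xpo1 itself rose (gene 103573, chromosome 11, 23255909 to 23297597; log2 fold change 0.86, SE 0.15, edgeR adjusted p = 0.00135), from 668 ± 46.8 to 1220 ± 31.5 CPM (SD, n = 2). Txnip, an inhibitor of thioredoxin and of glucose uptake, rose (3.09, SE 0.24, adjusted p = 2.6e-06), from 29 and 9.98 CPM to 212 and 94.3. With it rose Slc16a6, a monocarboxylate transporter (2.66, SE 0.24, adjusted p = 4.98e-06), Rgs9bp (4.32, SE 0.54, adjusted p = 8.31e-05), Fam26e (2.53, adjusted p = 9.31e-05) and Samd9l (3.03, adjusted p = 0.000281). Mfsd2a, a lipid transporter (-2.46, SE 0.22, adjusted p = 4.98e-06), and Areg, a ligand of the EGF receptor (-2.002, SE 0.18, adjusted p = 4.98e-06), fell. So did Egr3 (-2.55, SE 0.28, adjusted p = 3.17e-05), Pik3c2b (-1.88, adjusted p = 0.000121), Neat1, a nuclear long noncoding RNA (-1.99, adjusted p = 0.000568), and Hpdl (-1.98, adjusted p = 0.00249). Calls were lost by 2900060B14Rik (2.90) without untreated clone 14 (adjusted p = 0.0533) and by Has2, a hyaluronan synthase (-2.29), and A930013F10Rik (-1.87) without leptomycin B clone 12 (0.182 and 0.0518). They were also lost by Ypel4 (2.73) without leptomycin B clone 12 or either untreated library (0.084 to 0.124) and by Scarna17 (2.56) without leptomycin B clone 14 or either untreated library (0.0808 to 0.152). Ccnd1 was at -0.27 (SE 0.23, adjusted p = 0.506). edgeR called 1508 genes, 648 higher and 860 lower, with 190 and 165 at least 2-fold. Of these, 1497 had the same sign in both clones, and 3734 genes had an unadjusted p under 0.05. The count was 560 without untreated clone 12, 628 without leptomycin B clone 12, 649 without untreated clone 14, 48 without the clone block, 4494 when only the libraries compared were fitted and 2263 with DESeq2.

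Interferon response genes mostly had higher estimates with leptomycin B, and a part of them was called. Of them, 28 of 30 were positive and 9 rose, or 14 with 1 lower when adjusted over the list alone (camera adjusted p = 5.7e-05; adjusted p = 0.596 with an estimated correlation). Eif2ak2, the double-stranded RNA kinase PKR, rose (log2 fold change 0.81, SE 0.13, edgeR adjusted p = 0.000839) whichever library was left out. Ifit1 (2.07, adjusted p = 0.00174), Oasl1 (3.15, adjusted p = 0.000516) and Irf7 (2.83, adjusted p = 0.0049) rose as well. Oasl1 stood at 3.44 against 0.358 CPM there and at 0 in both clone 14 libraries. The calls of Ifit1, Oasl1 and Irf7 ended without leptomycin B clone 12 (adjusted p = 1, 0.808 and 0.111) or untreated clone 12 (0.247, 0.417 and 0.093). Immediate early and RAS-MAPK output genes moved both ways, with 2 of 15 higher and 4 lower, or 2 and 5 when adjusted over the list alone (camera adjusted p = 0.154). Fos rose (2.15, SE 0.32, edgeR adjusted p = 0.000345). Dusp5, an ERK phosphatase (-1.67, SE 0.23, adjusted p = 0.00024), and Egr1 (-1.19, SE 0.20, adjusted p = 0.00106) fell. Nuclear export and import genes were negative for 15 of 18 members, with 1 called higher and 2 lower, or 1 and 6 when adjusted over the list alone (camera adjusted p = 0.0185; adjusted p = 0.596 with an estimated correlation). Stress genes called higher included Ppp1r15a (1.34, adjusted p = 3.17e-05) and Ddit3 (0.80, adjusted p = 0.00107) of the integrated stress response and the chaperone Hspa1b (1.91, adjusted p = 0.000264), though neither list was called (camera adjusted p = 0.721 and 0.263). Tnfaip3, a brake on NF-kB, fell (-1.84, adjusted p = 4.98e-06), as did Sqle (-0.87, adjusted p = 0.00057) and Ccne1 (-0.82, adjusted p = 0.00177).

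**Figure D4:**
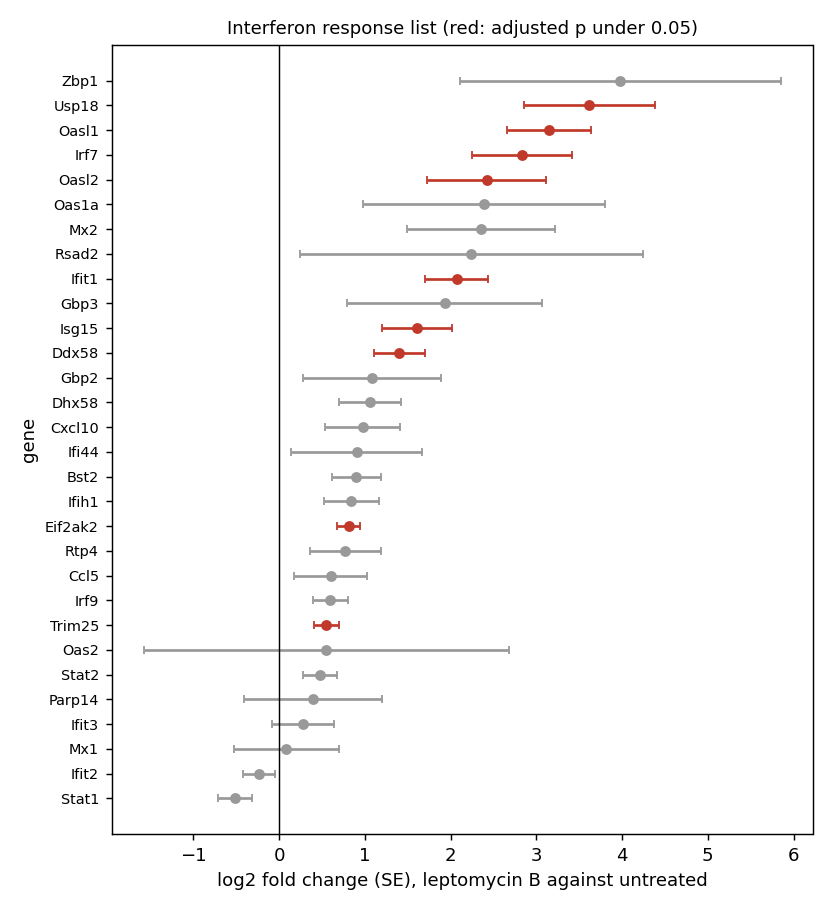
Log2 fold change with leptomycin B against no treatment for the 30 tested interferon response genes in tagged clones, as points with the standard error of the edgeR fit, red where the adjusted p is under 0.05. All but 2 genes lie above 0 and 9 are red, several of them with counts almost only in clone 12.

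SCR siRNA was compared with untreated cells of the tagged clones as the background of transfection. The untreated library of clone 12 carries a date in the labels that the siRNA libraries lack, so transfection and day cannot be told apart. F2r fell (log2 fold change -2.11, SE 0.13, adjusted p = 4.3e-08), from 281 ± 13.8 to 65 ± 0.0546 CPM (SD, n = 2). Cdkn1a rose (1.02, SE 0.15, adjusted p = 0.00123). So did Ddit3, a transcription factor of the integrated stress response (0.83, SE 0.14, adjusted p = 0.00219), Tcn2, a cobalamin carrier (2.25, SE 0.36, adjusted p = 0.00199), and Fabp3, a fatty acid binding protein (2.32, SE 0.36, adjusted p = 0.00157). Of 20 stress response genes 4 rose and 1 fell, or 10 and 3 when adjusted over the list alone (camera adjusted p = 0.0064; adjusted p = 0.596 with an estimated correlation). Of 20 extracellular matrix and contractile genes 3 rose, or 7 with 1 lower when adjusted over the list alone (camera adjusted p = 0.0064; adjusted p = 0.596 with an estimated correlation). Col3a1 was among them (0.92, edgeR adjusted p = 0.00563; 0.0619 without SCR clone 14 and 0.101 without untreated clone 14). Of 17 NF-kB targets 3 rose, or 4 when adjusted over the list alone (camera adjusted p = 0.036; adjusted p = 0.343 with an estimated correlation), such as the chemokine Ccl2 (1.73, edgeR adjusted p = 0.00671; 0.0781 without SCR clone 12 and 0.138 without untreated clone 14). Of 12 heat shock genes 2 rose, or 5 with 1 lower when adjusted over the list alone (camera adjusted p = 0.0207; adjusted p = 0.756 with an estimated correlation). Other strongly changed genes lost their calls without 1 or more of the 4 libraries. They were Sprr1a (2.97) and Mrgprf (2.62) without untreated clone 14 (adjusted p = 0.0714 and 0.106), and Serpinb1a (3.88) and Tac1 (2.90) without untreated clone 14 (0.234 and 0.46) or SCR clone 14 (0.166 and 0.354). They were also Zfp72 (-2.22) without SCR clone 12 (0.0952), Ampd3 (2.21) without SCR clone 12 (0.148) or untreated clone 14 (0.0501). Pcdh20 (-2.89), Pcdhb21 (-2.53) and Adamts12 (-2.14) lost theirs without SCR clone 12 (0.868, 0.184 and 0.667) or either untreated library, and Prl2c5 (2.23) without SCR clone 14 (0.738) or either untreated library. Ppm1e (-2.41) and 6030443J06Rik (-2.19) lost theirs without any one of the 4 (adjusted p up to 0.221 and 0.391). edgeR called 799 genes, 254 higher and 545 lower, with 99 and 175 at least 2-fold. Of these, 775 had the same sign in both clones, and 3707 genes had an unadjusted p under 0.05. Higher genes made up 31.8% of the calls, 39.6% with relative log expression size factors, 40.3% with a stricter filter, 45.1% with DESeq2 and 54.1% without SCR clone 12. Of the 799, 36 were at 0 in the SCR clone 12 library, and 858 were called among genes of at least 1 CPM. The count was 99 without untreated clone 14, 146 without SCR clone 12, 362 without untreated clone 12, 526 without SCR clone 14, 12 without the clone block and 1427 with DESeq2.

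Tagged and untagged clones were compared under SCR siRNA, with the clone as the replicate, to ask whether the tag itself went with a different transcriptome. No gene was called by edgeR (0 of 13233 genes). An unadjusted p under 0.05 was seen for 442, less than a 0.05 share of the genes tested. With 4 libraries this does not show that the transcriptomes were equal. DESeq2 called 177, edgeR without a filter on low counts 1, and a fit of all 18 siRNA libraries with no replicate block 5. Ccnd1 had a log2 fold change of -0.13 (SE 0.19), and differences between single clones were large in the principal components.

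Genes moved by tag and by cyclin D1 siRNA overlapped. In both, 251 were called with the same sign, 197 higher and 54 lower, against 15.7 for independent lists, and 1 with opposite signs. Both comparisons use the same SCR libraries. In the 12 tagged siRNA libraries alone, the correlation of the fold changes was 0.813 across genes, which are not independent replicates, against 0.679 in 20 simulations of unchanged groups (0.652 to 0.7). The covariance was 0.25 against 0.0717, a difference of 0.178. The same sign was seen in 73.4% of genes against 74.6% in simulation, and 141 genes were called in both. The simulations, with 0.05 and 0.2 calls on average for tag and cyclin D1 siRNA, do not bear on the number of shared calls. With 2 SCR libraries the controls could not be split, and part of the shared calls may come from them. Called with the same sign for all 5 siRNAs were 66 genes, 63 higher and 3 lower, among them Ccnd1 (mean log2 fold change -3.19), Cdkn1a (-1.13), Uhrf1 (-0.67), F2r (1.67), Taldo1 (1.71) and Fdps (0.68). Of such genes, 37 were called in the 12 libraries alone. Of the 66, 51 were also called with the same sign for tag siRNA in untagged clones, Cdkn1a, F2r, Taldo1 and Fdps among them. Uhrf1 was at -0.44 there (adjusted p = 0.0662). Without SCR clone 12, a setting chosen after seeing the data, 17 of the 66 remained.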

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

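The checks of the SCR control and of the loss of cyclin D1, the regroupings of clones, and the list without Ccnd1 were tests chosen after the result was seen.

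The response to tag siRNA differed between tagged and untagged clones at Ccnd1 (log2 difference -2.55, edgeR adjusted p = 0.000804). Camera called the D cyclins and G1 regulators (adjusted p = 0.017; adjusted p = 0.293 with an estimated correlation), which largely restates Ccnd1, since without it the list had an adjusted p of 0.299. Camera also called E2F targets (adjusted p = 0.0015; adjusted p = 0.806 with an estimated correlation), mitosis genes (0.00642; adjusted p = 0.807 with an estimated correlation) and epithelial markers (0.0361; adjusted p = 0.671 with an estimated correlation). The 4 clones can be split in 3 ways, too few for a share under 0.05. The real split gave 1 gene, 1 of the 3 splits gave as many, and the highest other gave 0.

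For the 404 genes that moved with FLAG and HA siRNA in clones without a tag to target, loss of cyclin D1 is argued against, since Ccnd1 changed by -0.147 there, with a fall of at most 0.538 within 2 standard errors. Whether an effect of the FLAG or HA sequence alone is the whole cause was not decided. Correlations between different siRNAs (0.785 and 0.797), over genes that are not independent replicates, reached 0.832 of those for the same siRNA (0.943 and 0.958). The genes were chosen by the mean of FLAG and HA siRNA, and every contrast subtracts SCR, which both favour a high value. A change made by the SCR control itself may account for part: of 107 genes also called between SCR and untreated cells, in other clones and with no shared library, 103, or 96.3%, went the opposite way, against 10.3 opposite for independent lists. These are 25.5% of the 404; called or not, 71.8% of the 404 had the opposite sign there, against 45.7% of all genes. Both arms of the untagged contrast were transfected, so an effect of transfection equal in both cancels there. Such an effect alone cannot give the calls in untagged clones. Whether transfection or day moved these 103 genes between SCR and untreated cells is not decided, since an equal effect leaves no trace in the untagged contrast. How far SCR siRNA itself moved genes in the untagged clones stays open, because those clones have no untreated library.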

How the results depend on the processing

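Untreated cells as control and the fits without Rn45s-rich libraries were chosen after seeing the data. Of 4154 recomputed values of the 267 named gene results, 1180 left-out-library and 2048 other values kept direction and side of the threshold, 508 and 397 fell below it, 8 and 12 turned direction and 1 passed it. Counts of called genes for tag siRNA in tagged clones, cyclin D1 siRNA, their difference, tag siRNA in untagged clones, leptomycin B and SCR against untreated were 32, 40, 88, 21, 48 and 12 with no replicate block, where the spread between clones enters the error, and 1024, 1280, 1676, 691, 2263 and 1427 with DESeq2. The block changed no other call besides those of single siRNAs, which without it were FLAG 13, HA 31, Qiagen 76, Nature 116, Life 116, untagged FLAG 14 and untagged HA 26. DESeq2 gave 606, 1139 and 1235 for FLAG, HA and Qiagen and 572 and 556 in untagged clones. With only the libraries compared, tag siRNA gave 3283, cyclin D1 siRNA 65, tag siRNA in untagged clones 80 and leptomycin B 4494. Without the libraries over 2% Rn45s, tag siRNA gave 377 and the difference 312. With untreated control, tag siRNA gave 4921 and cyclin D1 siRNA 3584. The mCherry constructs gave 2 genes without a filter and 15 with DESeq2. Tagged against untagged clones gave 1, 177, and 5 with 18 libraries and no replicate block. Gene list calls went from 27 to 0 with an estimated correlation, and to 25 without Ccnd1 in the lists.

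Leaving out 1 library gave 113 to 804 genes for tag siRNA in tagged clones, 97 to 1023 for cyclin D1 siRNA, 451 to 1510 for their difference, 27 to 380 in untagged clones, 0 to 28 for the tagged minus untagged response, 560 to 1088 for leptomycin B, 99 to 526 for SCR against untreated, and 0 to 0 for the mCherry constructs and for tagged against untagged clones; 17 of the 66 genes called with all 5 siRNAs remained without SCR clone 12. A lone library was assumed to vary like the other groups.

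Directions turned as follows. With untreated control they were, for tag siRNA, Ifi44 -0.493 and Tnfaip3 0.0904. For cyclin D1 siRNA they were F2r -0.391, Sprr1a 1.75, Cdkn1a 0.161, Ccnd3 0.0504, Hspd1 -0.0265, Eif2ak2 -0.121, Ifi44 -0.545 and Nes 0.169. Ccnd1 between constructs was -0.032 without Rn45s-rich libraries, -0.0263 without mCherry HA 2 and -0.0264 without the tagged HA 2 (highest 0.101). Ccnd1 for SCR against untreated was 0.018 with those libraries only, 0.0595 without SCR clone 12 and 0.292 without untreated clone 14 (lowest -0.308). With leptomycin B it was 0.0637 without leptomycin B clone 12 and 0.0541 without untreated clone 14 (lowest -0.75). Oasl1 with leptomycin B was -0.531 without its clone 12 (highest 3.26). Prl2c5 for SCR was -0.814 without SCR clone 14 (highest 5.06). The cause was not tested.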

Other observations

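The comparison of F2r across SCR libraries and the regroupings of the siRNAs and of the mCherry libraries were tests chosen after the result was seen.

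F2r, a thrombin receptor gene (gene 14062, chromosome 13, 95601780 to 95618466), was low in all 4 SCR libraries and in no other. It stood at 65 ± 0.0546 CPM (SD, n = 2) with SCR siRNA in tagged clones and at 69.1 and 102 in untagged clones, against 159 CPM or more in each of the other 24 libraries and 281 ± 13.8 in untreated cells. Against SCR it rose with each of the 5 siRNAs, by 1.42 with Life (edgeR adjusted p = 1.47e-06) to 1.91 with Qiagen on the log2 scale (3.34e-08), and against untreated cells it was at -0.39 with cyclin D1 siRNA (adjusted p = 0.00901). F2r is a candidate target of the SCR siRNA itself, a hypothesis from its values alone, as the sequence was not available here for a search.

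Cdkn1a, Ddit3, Col3a1, Ccl2 and Hspa1b were higher with SCR siRNA than without treatment, by 1.02, 0.83, 0.92, 1.73 and 1.48 on the log2 scale. Cdkn1a fell with each targeting siRNA against SCR, and against untreated cells it was at -0.51 with tag siRNA (adjusted p = 0.00671) and 0.16 with cyclin D1 siRNA (0.362). Ddit3 (0.80) and Hspa1b (1.91) also rose with leptomycin B, set against the same untreated libraries, so the rises with SCR and with leptomycin B are not independent.

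Genes that differ between SCR siRNA and untreated cells could come from the SCR sequence alone, or from transfection or another day. Of the 799 called, 572 (71.6%) were also called with the same sign for the mean of the other 5 siRNAs against untreated. Both comparisons use the same 2 untreated libraries, which alone can make calls overlap by an amount that was not simulated. The 71.6% therefore decides neither, and the explanations cannot be told apart here.

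Whether the difference between tag and cyclin D1 siRNAs comes from single sequences stays open. Of 3627 genes called for any of Qiagen (1919), Nature (847) or Life (1805) against FLAG and HA, 100 (2.76%) were called with the same sign for all 3, against 3.13 genes for independent lists, but the list sizes allow at most 23.4% and the lists share a reference, so the share decides nothing. For a deeper loss of cyclin D1, the slope of Qiagen minus HA on Nature and Life minus FLAG was 0.231 (SE 0.0339 over 438 genes, which are not independent replicates; 0.209 and 0.246 in the clones), neither 0 or below nor clearly above 0.25. Of 100 splits of the 10 libraries into 4 and 6, with the clone as block, 2 gave as many genes as the real 9, the real split and that of Nature and Life against the rest (highest other 9). Of the 10 groupings of the 5 siRNAs, 5 gave at least the real 1056, the real one included, and the highest other gave 3733.

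For the mCherry constructs, 10 of 10 splits of the 6 libraries gave as many genes as the real 0, which any split must, and the highest other gave 0, so the splits decide nothing.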
